A study of Mus musculus with 18 samples.

How the data were processed

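Total RNA from mouse uterus and ovary was sequenced in 18 libraries on an Illumina instrument with paired ends, after extraction with a Zymo kit, per the labels' protocols. Groups were taken from the labels for tissue and genotype (WT, ARE+/- or ARE-/-) and from the sample titles, which also carry a replicate number, giving 3 libraries for each of 3 genotypes in each of 2 tissues. The series' design text speaks of 3 mice per genotype, so the 3 libraries of a group were treated as separate animals. The labels do not say which uterus and ovary came from the same mouse. Titles mark uterus WT replicate 1 and ovary ARE-/- replicate 6 as backup samples; both were kept. No sequencing batch or date was given in the sources used here.

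The deposited count tables, 1 per tissue, hold whole-number counts per gene that the authors made with featureCounts 2.0.4 on the GENCODE M32 mouse annotation, per the file headers. The same headers show the options used: a read that maps to several places or overlaps several genes was counted for each, mates were counted singly, and no strand option was set. Genes with near-identical copies (Mup, H2-Q, Tgtp, Serpina3 and globin genes) and overlapping or antisense genes can therefore not be told apart with certainty. A read pair usually adds 2 counts, and 68.1% to 76.4% of the counts between 1 and 20 were even numbers. Reads were aligned with STAR, per the submitters' processing notes, which name the build mm10. GENCODE M32 is an annotation of the later mouse build, so the sources differ. Coordinates are given only as the annotation in the files states them. A GENCODE annotation of GRCm38 was at hand and was not used for coordinates, since 1298 of 51992 genes (2.5%) had the same start and end in both. The authors also deposited, per tissue, a table of a likelihood-ratio test made with DESeq2, per the submitters' processing notes, which lists all genes with a log2 fold change and an adjusted p-value where one was computed, and a cluster number for 514 of 514 uterus and 718 of 719 ovary genes under their threshold of 1e-04. The deposited log2 values do not state which genotypes they compare and entered no test here. The deposited p-values were only counted and compared with calls made here. The deposited cluster numbers, which group genes by their pattern over genotypes, were only tallied.

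Each table lists 57010 gene IDs, of which 38550 in the uterus and 39259 in the ovary had at least 1 count. A symbol was given for 52029 IDs (91.3%), which took 96.1% of uterus counts and 98.7% of ovary counts; no line of the tables was a total or an unassigned class. Totals per library were 33185496 to 49720354 counts. Mitochondrial transcripts took 2.79% to 4.72%. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 18.15 to 403.6 over genes), so no library was a copy of another of its group. Libraries of different groups were not compared in this way. All columns of per-sample values in the tables were used.

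Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling (factors 0.838 to 1.07 in the uterus and 0.978 to 1.03 in the ovary), and the robust quasi-likelihood F-test (glmQLFit, glmQLFTest) over the 9 libraries of a tissue with 1 mean per genotype. Common biological coefficients of variation were 0.411 in the uterus and 0.281 in the ovary. The 3 contrasts and a test of any genotype difference were made per tissue. The difference of the ARE-/- effect between tissues was tested as an interaction over all 18 libraries. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values of named genes use TMM-scaled library sizes, except for the Ifng levels per group, which use total counts. For a gene with 0 counts in all WT libraries a lower bound of the fold was computed against a floor of 3 counts over the WT group. With 1 to 3 WT counts a ratio with a 95% counting interval was given. These bounds and intervals treat the mates of a pair as independent counts, which they are not.

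Gene lists (38 lists of 9 to 35 genes, 525 distinct genes, 523 of them found; Ahsp and Dtprp were not matched) cover immune cell types, interferon responses, antigen presentation, ovarian and uterine cell types and functions, and other tissues that a sample could carry. They were tested with camera in limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over the lists of a contrast. In the uterus 23 lists passed for ARE-/- against WT, 7 with an estimated correlation; in the ovary 26 and 6. Named genes follow a rule written beforehand: Ifng; a fixed set of interferon, T cell, endometrial and ovarian genes whatever their result; the 5 largest rises and 5 largest falls for ARE-/- against WT, and 3 each for ARE+/- against WT and for the tissue difference, among called genes with a mean of at least 1 CPM whose groups do not overlap, leaving out unnamed and predicted genes and receptor segments; and up to 3 members with the smallest p of each list that passed camera. Prss28, of the fixed set, did not pass the count filter and has no value.

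The scripts were tested on simulated counts, drawn once per comparison from the real means, library sizes and edgeR's dispersions, with 200 changed genes. Recovery by edgeR of 2-fold and 4-fold changes for ARE-/- against WT and for the tissue difference is given with those comparisons. It was 9% and 55% in the uterus and 40% and 83% in the ovary for ARE+/- against WT, 5% and 48%, and 35% and 75%, for ARE-/- against ARE+/-, and 7% and 56%, and 43% and 77%, for any difference. The test by camera called the changed list and 0 of 37 unchanged lists. Simulated genes were drawn independently, so this says nothing about false calls for lists whose members vary together. Alternatives were size factors by relative log expression, no low-count filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, only the pair of genotypes compared, no robust estimation, the replicate number as a block, removal of 66 mitochondrial, hemoglobin and ribosomal RNA genes (5.32% of counts), glmTreat against a fold of 1.5, the authors' threshold, and leaving out each library in turn. Overlaps between contrasts that share WT libraries were set beside 20 simulations in which all 9 libraries were drawn from common means. Tables were made with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.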

Results

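RNA sequencing counts were analysed for 18 libraries of total RNA from the uterus and the ovary of C57B6/J mice aged 20 to 25 weeks. Each tissue was sampled in wild-type (WT), heterozygous (ARE+/-) and homozygous (ARE-/-) animals, with 3 libraries per tissue and genotype. ARE is the AU-rich element in the 3' untranslated region of Ifng, a stretch that shortens the life of the transcript of interferon gamma. This meaning is background, since the labels give the genotypes without defining the name. The series is about failed implantation, luteinization and CD8 T cells in such mice. The libraries held 33185496 to 49720354 counts in the uterus and 38132822 to 46647171 in the ovary. Each mate of a read pair was counted by itself. The stage of the estrous cycle was not given in the sources used here, so it was not a term in any test. Levels are CPM, counts scaled to a common library size, given as mean ± SD over the 3 libraries of a group, and log2 fold changes carry their standard errors. Genes are written as rising or falling where the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test was under 0.05. The genotype comparisons, gene lists and alternatives were fixed before the data were examined, while some tests of explanations were chosen later. In each ARE-/- or ARE+/- gene named below as rising or falling against WT, all 3 libraries lay on 1 side of all 3 WT libraries, which chance gives for 10% of genes.

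Ifng itself (ENSMUSG00000055170, chromosome 10, 118276951 to 118281797, plus strand, GENCODE M32 annotation in the files) followed the genotype labels in both tissues. In the uterus it had 4, 6 and 0 counts in WT replicates 1, 2 and 3, 58, 36 and 70 in the ARE+/- replicates, and 96, 130 and 56 in the ARE-/- replicates. In the ovary it had 4, 0 and 4 counts in WT replicates 1, 2 and 3, 18, 10 and 28 in ARE+/- replicates 1, 2 and 4, and 51, 38 and 50 in ARE-/- replicates 2, 3 and 6. The library with 0 counts in the uterus, WT 3, allowed a level of up to 0.0697 CPM, and that in the ovary, WT 2, up to 0.0771 CPM, both from the floor of 3 counts. Mean levels on total counts were 0.0796 ± 0.0702, 1.36 ± 0.508 and 2.39 ± 0.787 CPM in WT, ARE+/- and ARE-/- uterus, and 0.0683 ± 0.0591, 0.469 ± 0.253 and 1.14 ± 0.173 CPM in the ovary (SD, n = 3 each). Ifng rose in ARE-/- uterus by a log2 fold change of 4.93 ± 0.80 (edgeR adjusted p = 0.011) and in ARE-/- ovary by 4.04 ± 0.80 (adjusted p = 0.013). In ARE+/- animals it rose in the uterus (4.01 ± 0.79, adjusted p = 0.047), while the ovary value of 2.73 ± 0.80 was not called (adjusted p = 0.13). The ARE-/- calls ended without WT replicate 1, in the uterus (5.18, adjusted p = 0.0665) and in the ovary (4.42, adjusted p = 0.0507). The ARE+/- call in the uterus ended without any 1 of 7 libraries, with values from 3.44 to 4.59 and adjusted p from 0.0525 to 0.208. Counting the other settings too, that call was lost in 10 of 19 alternatives. Intervals and floors in the text cover counting error only, and they take each count as independent. Both mates of a read pair were usually counted, so the intervals are too narrow, the floors too low and the fold bounds too high.

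**Figure D1:**
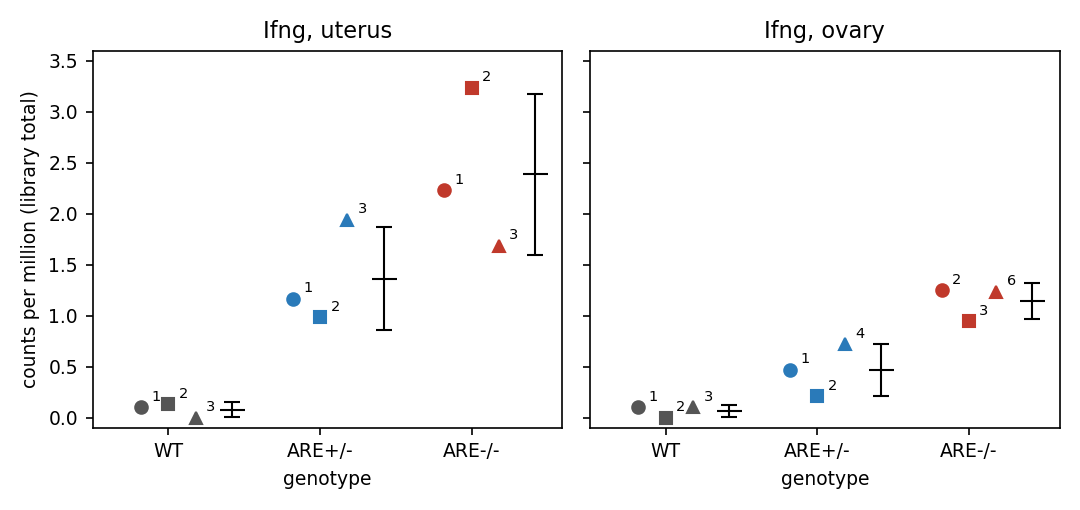
Ifng level in CPM on total counts (vertical axis) by genotype (horizontal axis) in uterus and ovary; each point is 1 library with its replicate number, and the black bar is the mean ± SD of 3. The WT libraries lie near 0 in both panels and every ARE+/- and ARE-/- library lies above them.

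The first question was what the loss of both ARE copies does to the uterus. The ARE-/- uterus showed a broad rise of genes that interferon gamma induces. Cxcl9, a chemokine that draws activated T cells, rose from 1.48 ± 0.210 CPM in WT to 81.8 ± 29.9 CPM (log2 fold change 5.79 ± 0.38, edgeR adjusted p = 0.00052). Cxcl10, a chemokine for the same receptor, Gbp2, a guanylate-binding protein, and Iigp1, an immunity-related GTPase, rose by 3.99, 3.26 and 4.27 on the log2 scale (adjusted p = 0.0026, 0.0014 and 0.00059). Cd274, which encodes the checkpoint ligand PD-L1, went from 3.76 ± 0.600 to 41.4 ± 5.66 CPM (3.46 ± 0.26, adjusted p = 0.00059). Of the 35 measured genes of the interferon gamma response list, 33 rose and 0 fell (34 rose when adjusted over the list alone), with a median log2 fold change of 3.14 (camera adjusted p = 1.1e-118, adjusted p = 0.0099 with an estimated correlation). Antigen presentation moved with it. Of 17 MHC class I genes 16 rose (17 adjusted over the list alone, median 2.44, adjusted p = 0.0099 with an estimated correlation), among them H2-K1, a classical class I heavy chain (519 ± 35.9 to 3545 ± 695 CPM, 2.77 ± 0.26, adjusted p = 0.00078). Of 10 class II genes 9 rose (10 adjusted over the list alone, median 3.01, adjusted p = 0.0099 with an estimated correlation), with H2-Aa at 3.00 ± 0.28 (adjusted p = 0.00079) and Ciita, the class II transactivator, at 2.99 ± 0.37 (adjusted p = 0.0026). Of 20 genes on the type I interferon list 3 rose (16 adjusted over the list alone, median 1.43). This list's camera call (adjusted p = 9.2e-12) was lost with an estimated correlation, at adjusted p = 0.16. Without WT replicate 1 or WT replicate 3 the type I genes called fell from 3 to 0, whereas 29 to 33 interferon gamma response genes were called when any single library was left out.

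Transcripts of CD8 T cells were higher in the ARE-/- uterus. Cd8a, the alpha chain of the CD8 co-receptor, rose from 0.376 ± 0.160 to 15.7 ± 2.20 CPM (5.36 ± 0.38, edgeR adjusted p = 0.00052), Cd8b1, its partner chain, by 5.18 ± 0.42 (adjusted p = 0.00059), and Cd3e, part of the T cell receptor complex, from 1.79 ± 0.279 to 13.1 ± 3.55 CPM (2.87 ± 0.30, adjusted p = 0.001). Cd4 rose by 2.39 ± 0.39 (adjusted p = 0.01), a call that ended without WT replicate 3 (2.36, adjusted p = 0.0731). Gzmb, the cytotoxic protease granzyme B, was at 15.8 ± 9.19 CPM in WT and 14.3 ± 8.28 CPM in ARE-/- uterus and was not called (-0.15 ± 0.58, adjusted p = 0.92). Its sign turned without WT replicate 2 (0.43), ARE-/- replicate 1 (0.09) or ARE-/- replicate 3 (0.05). Of 14 T cell receptor complex genes 13 rose (13 adjusted over the list alone, median 2.39, adjusted p = 0.011 with an estimated correlation), and of 16 CD8 and cytotoxic genes 9 rose (13 adjusted over the list alone, median 1.72, adjusted p = 0.03 with an estimated correlation). Regulatory and CD4 genes gave 3 rises of 9 (adjusted p = 0.021 with an estimated correlation). The natural killer list did not pass, with 0 rises and 1 fall of 10 (camera adjusted p = 0.67). The fall was Klra8, a Ly49 receptor (-2.21 ± 0.48, adjusted p = 0.037). Ighm, the immunoglobulin M heavy chain, rose by 2.77 ± 0.23 (adjusted p = 0.00059), and 2 of 15 B and plasma cell genes rose (7 adjusted over the list alone, adjusted p = 0.0099 with an estimated correlation). Macrophage genes gave 11 rises of 16 and complement genes 8 of 12, each at adjusted p = 0.068 with an estimated correlation. Among them Lyz2, lysozyme of macrophages and neutrophils, rose by 1.80 ± 0.24 (adjusted p = 0.0045) and C4b, a complement component, from 112 ± 12.1 to 1045 ± 514 CPM (3.22 ± 0.45, adjusted p = 0.0053). Csf3r, the receptor of a neutrophil growth factor, rose by 2.81 ± 0.40 (adjusted p = 0.0063), and this call ended without WT replicate 3 (2.75, adjusted p = 0.0524). Left out singly, WT replicates 1 and 3 took the macrophage calls from 11 to 2 and the complement calls from 8 to 3. T cell receptor calls went to 8 with either, CD8 and cytotoxic calls to 5 and 4, CD4 calls to 1 and 0, and B and plasma cell calls to 1.

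The steroid-responsive genes that prepare the uterus for implantation were not called. This does not show that they were unchanged. In simulations of this comparison edgeR recovered 5% of 2-fold and 54% of 4-fold changes, and the stage of the estrous cycle was not given. Pgr, the progesterone receptor, was at 291 ± 149.9 CPM in WT and 119 ± 111 CPM in ARE-/- uterus (-1.28 ± 0.63, edgeR adjusted p = 0.3), and Esr1, the estrogen receptor, gave -0.82 ± 0.32 (adjusted p = 0.2). Ihh, a progesterone-induced signal of the epithelium, gave -0.67 ± 0.75, Lif, a cytokine needed for implantation, -0.61 ± 0.65, and Areg, an epidermal growth factor family ligand, -0.86 ± 1.43 (adjusted p = 0.67, 0.66 and 0.79). Without WT replicate 2 the values of Ihh and Areg turned to 0.64 and 2.77. Ltf, lactotransferrin, an estrogen-induced secretory protein, was at 369.5 ± 247 CPM in WT and 2385 ± 1729 CPM in ARE-/- uterus (2.69 ± 0.72, adjusted p = 0.076). Lcn2, a secreted iron-binding protein, Foxa2, a gland transcription factor, and Mki67, a proliferation marker, gave 2.05 ± 1.52, 0.28 ± 0.34 and -0.50 ± 0.42 (adjusted p = 0.5, 0.7 and 0.55), with Lcn2 at -0.48 without ARE-/- replicate 3 and Foxa2 at -0.04 without ARE-/- replicate 2. None of the 22 measured genes of the progesterone and receptivity list was called (median -0.53, camera adjusted p = 0.12), nor any of 20 estrogen response genes (median 1.18, adjusted p = 0.1; 7 higher and 2 lower adjusted over the list alone), 10 gland genes (adjusted p = 0.74) or 9 decidua genes (adjusted p = 0.74). Proliferation genes moved lower as a list (0 of 20 called, median -0.50, camera adjusted p = 0.0016), which was lost with an estimated correlation (adjusted p = 0.63).

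Collagen genes were lower in the ARE-/- uterus. Col1a1 fell from 5792 ± 1650.0 to 1932 ± 605 CPM (-1.58 ± 0.37, edgeR adjusted p = 0.045), and Col1a2 and Col6a3 fell too, making 3 of 15 matrix genes (9 adjusted over the list alone, median -1.07, adjusted p = 0.11 with an estimated correlation). No matrix gene was called without WT replicate 1, WT replicate 3, ARE+/- replicate 1, ARE+/- replicate 2, ARE-/- replicate 1 or ARE-/- replicate 3. Fat cell and red cell transcripts were higher in these same libraries. Plin1, a coat protein of lipid droplets, rose from 3.71 ± 1.02 to 277 ± 317 CPM (6.22 ± 0.88, adjusted p = 0.0071), and 9 of 9 adipocyte genes rose (median 6.42, adjusted p = 0.068 with an estimated correlation). Hba-a2, an alpha globin, was at 890.2 ± 1050.0 CPM against 45.3 ± 15.9 CPM in WT, and 5 of 6 erythroid genes rose (adjusted p = 0.14 with an estimated correlation). Near-identical globin copies share reads, so their separate values are uncertain. Without WT replicate 1 or WT replicate 3 the adipocyte and erythroid calls fell to 0 (erythroid calls to 1 without WT replicate 2 or ARE+/- replicate 2), and without ARE-/- replicate 1 the adipocyte calls were 8. In ARE-/- replicate 1 hemoglobin took 0.606% of the counts, against 0.133% and 0.0836% in ARE-/- replicates 2 and 3 and at most 0.0234% in the other uterus libraries. That library also held transcripts abundant in the ovary, such as Inha, an inhibin subunit chosen after its values were seen, at 118 CPM against at most 13.7 CPM in any other uterus. Mast cell proteases were lower, with Cma1, mast cell chymase, at 5.89 ± 1.48 CPM in WT and 0.649 ± 0.579 CPM in ARE-/- uterus (-3.17 ± 0.94, adjusted p = 0.1). Of 7 mast cell genes 0 were called (4 lower adjusted over the list alone), and the list's camera call (adjusted p = 4.5e-05) was lost with an estimated correlation (adjusted p = 0.068).

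The 5 largest rises by the rule in the ARE-/- uterus were Mup14, Mup13, Mup2, Serpina3j and Ttc6. Mup14 and Mup13, major urinary proteins, had 0 counts in the 3 WT libraries and 813 and 809 counts in the ARE-/- libraries, at least 309-fold and 307-fold higher against a floor of 3 counts over the WT group. Mup2 had 1 WT count and a ratio of 922 (95% counting interval 165 to 36400). The Mup genes are near-identical copies that share reads, so which of them rose is uncertain. Serpina3j, a serine protease inhibitor from another family of copies, was at least 229-fold higher and Ttc6 at least 124-fold higher. Both calls ended without WT replicate 1 (adjusted p = 0.0904 and 0.142) or WT replicate 3 (0.0909 and 0.148). The call of Serpina3j was lost in 3 of 19 alternatives and that of Ttc6 in 11 of 17. The largest falls were Galnt13 (-4.27 ± 0.98), a sugar transferase, Chst13 (-4.24 ± 0.96), a sulfotransferase, Adgrb3 (-3.15 ± 0.74) and Gpr83 (-2.94 ± 0.62), both membrane receptors, and Chn1os1 (-2.82 ± 0.66), with adjusted p from 0.032 to 0.049. Their calls were lost in 7 to 14 of 19 alternatives, including the removal of WT replicate 1 (adjusted p 0.122 to 0.195) and of WT replicate 3 (0.134 to 0.200). Across 24277 genes tested, 911 passed: 816 were higher and 95 lower, and 855 of them differed at least 2-fold. The number of lower genes was 1 and 2 without WT replicates 1 and 3, 375 without WT replicate 2 and 278 without ARE-/- replicate 2, so the balance of rises and falls, 70.4% to 99.5% higher, depended on single libraries. The total was 203 without WT replicate 1, 192 without WT replicate 3, 603 without ARE+/- replicate 1 and 552 without ARE+/- replicate 2. DESeq2 gave 2407, but on simulated data 35.8% of its calls fell on unchanged genes, against 4.8% for edgeR. The simulation was a single draw with edgeR's dispersions, so these shares may favour edgeR and need not hold for the real counts. In it edgeR recovered 54% of genes changed 4-fold and 5% of genes changed 2-fold, so small changes may often be missed at this number of libraries.

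The ARE+/- uterus was compared with WT to ask whether 1 altered copy is enough. Interferon gamma response and antigen presentation genes were higher here too, with smaller medians than in the ARE-/- uterus. Cxcl9 rose to 15.7 ± 4.78 CPM (3.41 ± 0.34, edgeR adjusted p = 0.0056) and Cd8a to 4.38 ± 0.628 CPM (3.52 ± 0.35, adjusted p = 0.0056). By contrast Cd3e (1.32 ± 0.29, adjusted p = 0.065) and Cd4 (1.25 ± 0.38, adjusted p = 0.16) were not called. Of the interferon gamma response genes 27 of 35 rose (33 adjusted over the list alone, median 2.25), of class I genes 13 of 17 and of class II genes 8 of 10, each list at adjusted p = 0.03 with an estimated correlation. T cell receptor genes gave 4 rises of 14 and CD8 and cytotoxic genes 3 of 16 (13 and 8 adjusted over the list alone), each at adjusted p = 0.089 with an estimated correlation. Type I interferon genes gave 2 rises of 20 (17 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation), at a median of 1.56 against 1.43 in the ARE-/- uterus. Csf3r rose by 2.98 ± 0.41 (adjusted p = 0.01), and Gabrp, a receptor subunit of the estrogen response list, by 2.83 ± 0.47 (adjusted p = 0.027). Adipocyte genes were at a median of 2.74 with 0 of 9 called (8 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation). Mup14 and Mup13 had 0 WT counts and were at least 55.1-fold and 52.5-fold higher. Both calls were lost in 3 of 19 alternatives. The largest falls were Dscam (-4.72 ± 0.88), Emb (-2.08 ± 0.39) and Kcne4 (-1.80 ± 0.36), at adjusted p of 0.039, 0.041 and 0.048, and their calls were lost in 9, 11 and 9 of 19 alternatives (adjusted p of up to 0.242). In all, 276 genes passed, 263 higher and 13 lower. The edgeR count was 4 without WT replicate 1 and 0 without WT replicate 3 (2113 genes at an unadjusted p under 0.05; DESeq2 and limma-voom were not run without that library). It was 529 without WT replicate 2, 131, 124 and 122 without ARE+/- replicates 1, 2 and 3, and 733 and 432 without ARE-/- replicates 1 and 3.

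ARE-/- and ARE+/- uteri were then set against each other. No gene passed in edgeR, with 1182 genes at an unadjusted p under 0.05, 0 called by limma-voom and 186 by DESeq2. Several lists were higher in the ARE-/- uterus. The largest median shifts were in erythroid genes (4.30, 6 of 6 adjusted over the list alone, camera adjusted p = 7.1e-23, adjusted p = 0.07 with an estimated correlation) and adipocyte genes (3.71, 8 of 9, camera adjusted p = 4.8e-20, adjusted p = 0.094 with an estimated correlation). The interferon gamma response genes were higher too, with a median of 0.86 and 23 of 35 passing when adjusted over the list alone (camera adjusted p = 5.3e-43), a call lost with an estimated correlation (adjusted p = 0.07). T cell receptor genes had a median of 1.28 and 13 of 14 passed adjusted over the list alone (adjusted p = 0.062 with an estimated correlation). Cd8a was at 4.38 ± 0.628 CPM in ARE+/- and 15.7 ± 2.20 CPM in ARE-/- uterus, a difference of 1.84 ± 0.32 that was not called (adjusted p = 0.47).

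In the ovary the question was whether the same genes rose and what became of the follicle and the corpus luteum. The ARE-/- ovary had the interferon pattern. Cxcl9 rose from 0.796 ± 0.260 to 84.2 ± 21.6 CPM (6.72 ± 0.36, edgeR adjusted p = 1.8e-05), and Gbp2b from 0.101 ± 0.133 to 32.2 ± 8.63 CPM (8.27 ± 0.84, adjusted p = 0.0016). Cxcl10, Gbp2 and Iigp1 rose by 3.46, 2.85 and 4.39 (adjusted p = 0.00032, 4.2e-06 and 6.1e-05). Ubd, a ubiquitin-like modifier that interferon induces, had 0 counts in WT ovary and was at least 406-fold higher in ARE-/- ovary. All 34 measured interferon gamma response genes rose (median 3.18, the same with Ubd at its lower bound; adjusted p = 0.0039 with an estimated correlation), as did 16 of 17 class I genes (adjusted p = 0.0039 with an estimated correlation) and 10 of 10 class II genes (adjusted p = 0.012 with an estimated correlation). Tap1, a peptide transporter for class I, rose by 3.14 ± 0.11, H2-K1 by 3.15 ± 0.13, H2-Aa by 3.05 ± 0.24 and Ciita by 3.54 ± 0.18 (adjusted p = 1.5e-06, 2.2e-06, 0.00014 and 3.7e-06), and the class II chain H2-Eb2 by 5.75 ± 0.75 (adjusted p = 0.0026). Type I interferon genes gave 15 rises of 20 (19 adjusted over the list alone), at adjusted p = 0.093 with an estimated correlation.

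Lymphocyte transcripts rose in the ARE-/- ovary. Cd8a went from 0.558 ± 0.0847 to 9.28 ± 2.76 CPM (4.05 ± 0.31, edgeR adjusted p = 6.2e-05), Cd3e rose by 3.00 ± 0.44 (adjusted p = 0.0036), and Cd4 by 2.00 ± 0.37 (adjusted p = 0.01; 1.88 and 0.0573 without WT replicate 1). Gzmb rose from 0.473 ± 0.239 to 3.89 ± 1.06 CPM (3.03 ± 0.51, adjusted p = 0.0067), Nkg7, a cytotoxic granule protein, by 3.72 ± 0.34 (adjusted p = 0.00022), and Ccl5, a chemokine that T cells secrete, by 4.37 ± 0.38 (adjusted p = 0.0002). In all 14 of 16 CD8 and cytotoxic genes rose (16 adjusted over the list alone, adjusted p = 0.044 with an estimated correlation), and 13 of 14 T cell receptor genes did (adjusted p = 0.093 with an estimated correlation). Natural killer genes gave 6 rises of 10, macrophage genes 12 of 16 and eosinophil genes 3 of 6, each at adjusted p = 0.093 with an estimated correlation. Examples are Cx3cr1, a chemokine receptor of macrophages (1.65 ± 0.13, adjusted p = 8.9e-05), and Ccr3, the eotaxin receptor (4.83 ± 0.75, adjusted p = 0.0047). Xcr1, the receptor of cross-presenting dendritic cells, rose by 4.05 ± 0.55 (adjusted p = 0.0035), 1 of 3 rises among 10 dendritic cell genes (adjusted p = 0.13 with an estimated correlation). Among death receptor and caspase genes 10 of 14 rose (adjusted p = 0.044 with an estimated correlation), including Zbp1, a sensor that starts necroptosis (4.05 ± 0.31, adjusted p = 0.00014), and Gsdmd, the pore former of pyroptosis (1.21 ± 0.13, adjusted p = 0.00077). Left out singly, WT replicate 1 took natural killer calls to 1, macrophage calls to 8, eosinophil calls to 1, dendritic cell calls to 2 and death receptor calls to 4. Immunoglobulin transcripts took 0.0143% to 0.0293% of the counts in WT ovaries and 0.161%, 0.410% and 0.0309% in ARE-/- replicates 2, 3 and 6.

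Genes of luteal steroid synthesis were lower in the ARE-/- ovary without passing gene by gene. Star, which carries cholesterol into mitochondria, was at 1420.0 ± 1594 CPM in WT and 238 ± 239 CPM in ARE-/- ovary (-2.58 ± 1.24, edgeR adjusted p = 0.24). Cyp11a1, the first enzyme of steroid synthesis, was at 4928 ± 484 and 2325 ± 1922 CPM (-1.08 ± 0.62, adjusted p = 0.32), and Akr1c18, which breaks down progesterone, at 516 ± 544 and 12.4 ± 12.4 CPM (-5.38 ± 2.29, adjusted p = 0.19). Lhcgr, the luteinizing hormone receptor, gave -0.80 ± 0.69, Prlr, the prolactin receptor, -1.62 ± 0.65, Ptgfr, the prostaglandin F receptor, -2.13 ± 1.28, Sfrp4, a Wnt antagonist of the corpus luteum, -2.32 ± 1.37, and Hsd3b1, a steroid dehydrogenase, -0.28 ± 0.33 (adjusted p = 0.52, 0.17, 0.35, 0.34 and 0.65). The corpus luteum and steroidogenesis list as a whole lay lower (0 of 20 called, median -0.91, camera adjusted p = 0.00087), a call lost with an estimated correlation (adjusted p = 0.34). Cholesterol synthesis genes did likewise (median -0.89, 1 of 22 fell, camera adjusted p = 5.4e-05, adjusted p = 0.41 with an estimated correlation). Libraries of a group were far apart here. The mean log2 CPM of the luteal list was 8.61, 8.40 and 8.07 in WT replicates 1, 2 and 3, 7.75, 8.28 and 6.82 in ARE+/- replicates 1, 2 and 4, and 7.01, 6.02 and 7.84 in ARE-/- replicates 2, 3 and 6. The difference of -1.40 between group means had an exact permutation p of 0.1 (two-sided, n = 3 each), the smallest that 3 against 3 allows. Without ARE-/- replicate 6, 6 luteal and 6 cholesterol genes fell, with a luteal median of -1.89. Without ARE-/- replicate 2 or 3 none of either list fell, with luteal medians of -0.80 and -0.72. Follicle genes were not called. Fshr, the receptor of follicle-stimulating hormone, gave -0.98 ± 0.58, Cyp19a1, aromatase, -1.14 ± 1.24, Cyp17a1, an androgen-making enzyme of theca cells, -2.23 ± 0.79, and Mki67 0.15 ± 0.19 (adjusted p = 0.33, 0.62, 0.13 and 0.68). Gdf9, an oocyte growth factor, gave 0.17 ± 0.38 (adjusted p = 0.82), and without ARE-/- replicate 6 Gdf9 and Mki67 turned to -0.41 and -0.11. Of 20 oocyte genes 0 were called (median 0.06).

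Transcripts of the mitochondrial genome were lower in the ARE-/- ovary. mt-Nd5, a subunit of respiratory complex I, fell from 2375 ± 164 to 1404 ± 132 CPM (-0.76 ± 0.10, edgeR adjusted p = 0.0028), and 10 of 13 such genes fell (median -0.58, camera adjusted p = 1.7e-09, adjusted p = 0.18 with an estimated correlation). On the list of ovarian surface and oviduct epithelium 8 of 12 genes rose (adjusted p = 0.093 with an estimated correlation). The keratin gene Krt19 was at 1.21 ± 0.15 (edgeR adjusted p = 0.0017). Ovgp1, a secreted glycoprotein of the oviduct, rose from 1694 ± 328 to 3080.0 ± 255 CPM (0.86 ± 0.15, edgeR adjusted p = 0.008). Other members differed: Lgr5 was at -1.15, Upk1b at 0.39 and Msln at 0.56 in the fit over all 18 libraries. Whether the ovary samples held differing amounts of oviduct was not tested. Uterine gland, uterine estrogen response and smooth muscle lists were higher in these ovaries too, with 2 of 9, 3 of 17 and 1 of 12 genes rising and 1 estrogen response gene falling (camera adjusted p = 0.018, 0.034 and 0.035), all lost with an estimated correlation (adjusted p = 0.34, 0.43 and 0.61). The largest falls by the rule were Cd209f (-2.75 ± 0.62), Nxf3 (-1.97 ± 0.51), Tmem71 (-1.94 ± 0.38), Lix1 (-1.86 ± 0.28) and Corin (-1.85 ± 0.36), at adjusted p from 0.0039 to 0.038. All but Lix1 lost their calls without WT replicate 1 (adjusted p from 0.0554 to 0.103). Among the largest rises, Cyp1a1, a xenobiotic-metabolising enzyme, had 2 WT counts and a ratio of 234 (95% counting interval 64.5 to 1940), with a call lost in 9 of 18 alternatives. Of 24457 genes tested 2558 passed in edgeR, 1544 higher and 1014 lower, and 991 of them differed at least 2-fold. The count was 785 without WT replicate 1, of which 780 were among the 2558, 1480 and 1219 without WT replicates 2 and 3, and 1337 without ARE-/- replicate 2. Without WT replicate 1, 6 mitochondrial and 5 epithelial genes were called. In simulations of this comparison edgeR recovered 77% of genes changed 4-fold and 37% of genes changed 2-fold.

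**Figure D2:**
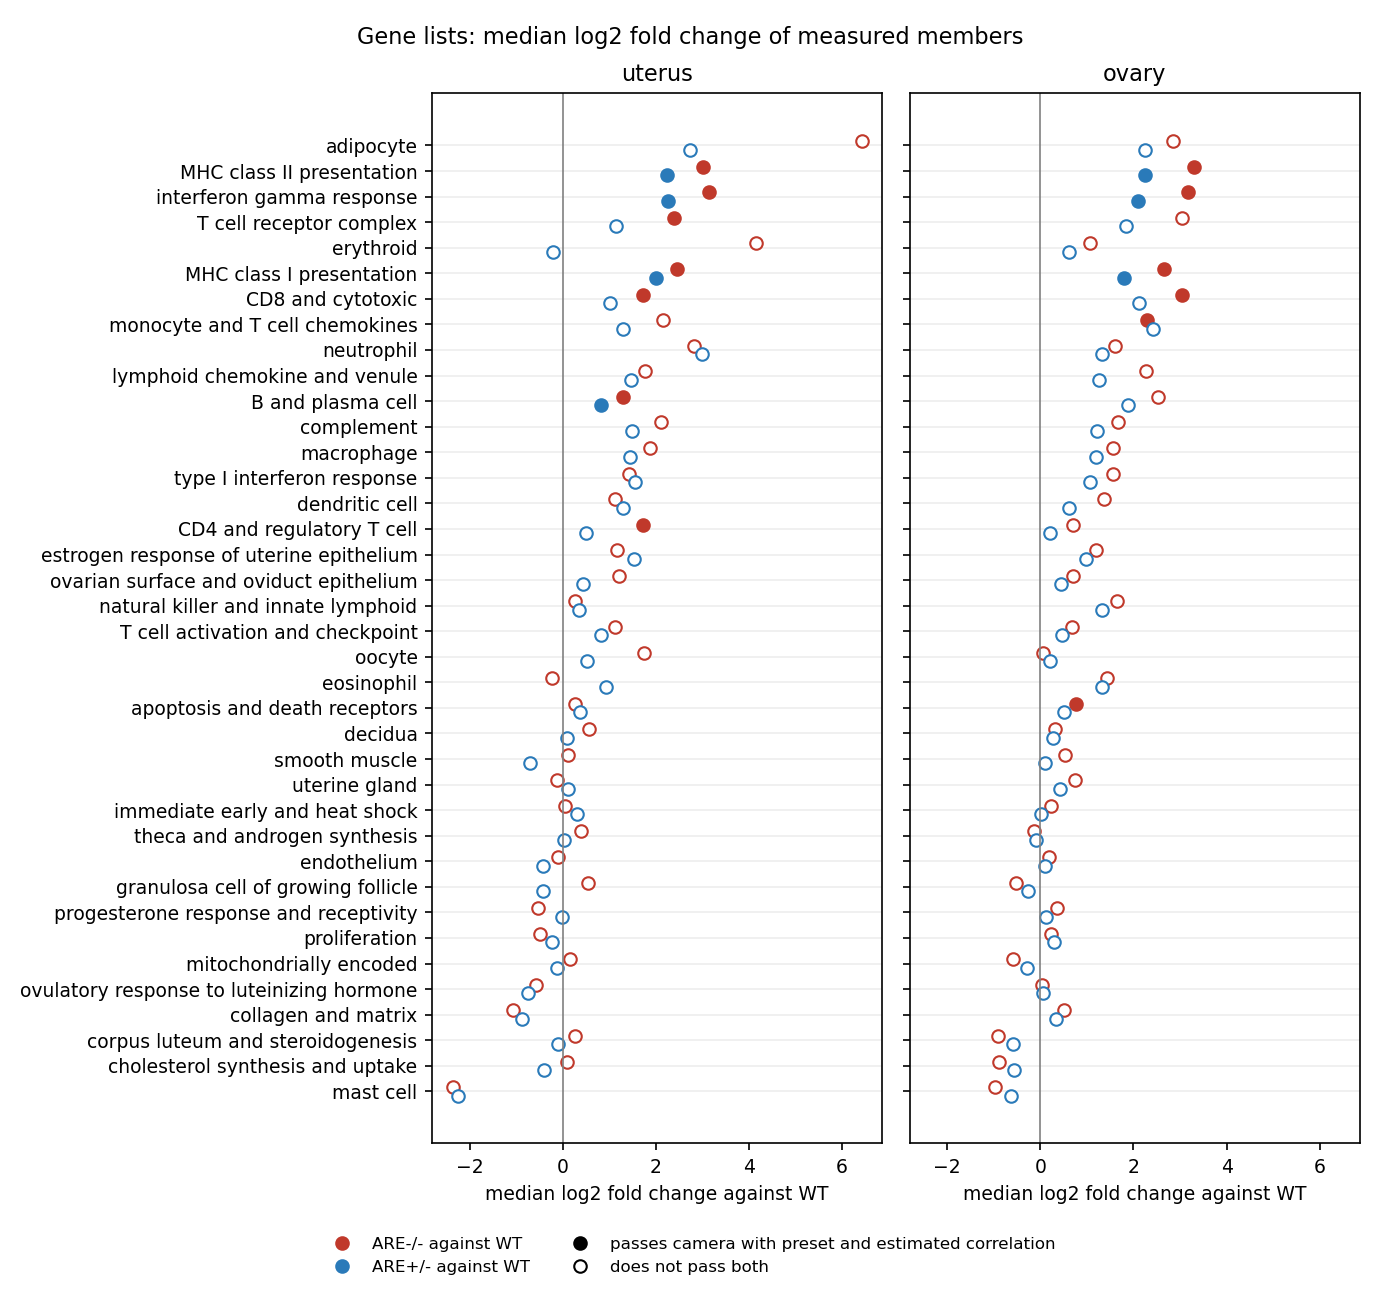
Median log2 fold change of the measured members of 38 gene lists (vertical axis) against WT (horizontal axis, log2) for ARE-/- (red) and ARE+/- (blue) in uterus and ovary; filled points passed camera with both the preset and the estimated correlation. The interferon gamma response medians are 3.14 and 2.25 in the uterus and 3.18 and 2.11 in the ovary, and the luteal list lies at -0.91 in the ARE-/- ovary.

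The ARE+/- ovary was compared with WT in the same way. Cxcl9 rose to 27.5 ± 7.56 CPM (5.10 ± 0.34, edgeR adjusted p = 0.00016) and Cd8a to 3.52 ± 0.780 CPM (2.65 ± 0.30, adjusted p = 0.0023), while Cd3e was not called (1.79 ± 0.43, adjusted p = 0.07). Ubd was at least 116-fold higher than in WT ovary. Its call ended without any 1 of 6 libraries, at adjusted p of up to 0.126, and was lost in 9 of all 19 alternatives. Interferon gamma response genes gave 30 rises of 34 and class I genes 15 of 17, both at adjusted p = 0.0043 with an estimated correlation, and class II genes 8 of 10 (adjusted p = 0.016 with an estimated correlation). CD8 and cytotoxic genes gave 8 rises of 16 (15 adjusted over the list alone, adjusted p = 0.069 with an estimated correlation). The luteal list had a median of -0.59 with 0 of 20 called (camera adjusted p = 0.01, adjusted p = 0.47 with an estimated correlation). The largest falls were Grin2c, a glutamate receptor subunit (-1.50 ± 0.18, adjusted p = 0.0038), Kcnt2, a potassium channel (-0.92 ± 0.17, adjusted p = 0.034), and mt-Nd3 (-0.85 ± 0.13, adjusted p = 0.015). In all 417 genes passed, 330 higher and 87 lower. The count was 75, 145 and 90 without WT replicates 1, 2 and 3, 89 and 112 without ARE+/- replicates 1 and 4, and 250 and 727 without ARE-/- replicates 2 and 6. The call of Kcnt2 ended without any 1 of 6 libraries (-0.80 to -1.05) and that of mt-Nd3 without WT replicate 1 (-0.86) or WT replicate 2 (-0.83). Over all alternatives calls were lost in 1 of 19 for Grin2c, 8 of 19 for Kcnt2 and 4 of 18 for mt-Nd3.

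Between ARE-/- and ARE+/- ovaries 12 genes passed in edgeR, all higher in ARE-/- and at adjusted p from 0.0448 to 0.0487, with 2051 genes at an unadjusted p under 0.05. They were Irgm1, Ifi47, Tgtp1, Tgtp2 and Gm12185, genes of the interferon-inducible GTPases and their neighbourhood, H2-K1, H2-Q4, H2-Q6 and H2-Q7, class I heavy chains, and Psmb8, Psmb9 and Tap1, which make and carry class I peptides. They are named because they are all of the 12, after their values were seen. Irgm1 rose by 1.01 ± 0.10 and H2-K1 by 1.03 ± 0.12. Tgtp1 with Tgtp2, and the H2-Q genes, are copies that share reads and are uncertain one by one. Of 34 interferon gamma response genes 7 rose (34 adjusted over the list alone, median 1.00, adjusted p = 0.028 with an estimated correlation). The 12 calls sat close to the threshold. No gene was called with a mean CPM of at least 1, with the pair of genotypes alone or without robust estimation, whereas limma-voom gave 19 and DESeq2 199. The count was 0 without WT replicate 1, any of the 3 ARE+/- replicates or ARE-/- replicate 3, and 5, 7 and 2 without WT replicate 2, WT replicate 3 and ARE-/- replicate 2.

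A test of any genotype difference within a tissue called 546 genes in the uterus and 1285 in the ovary (edgeR, Benjamini-Hochberg 0.05), with 3802 and 5129 at an unadjusted p under 0.05. Without WT replicates 1 and 3 in turn the uterus count was 84 and 90, and without ARE+/- replicates 1, 2 and 3 it was 254, 215 and 354. The ovary count was 210, 480 and 406 without WT replicates 1, 2 and 3, 740 without ARE+/- replicate 1 and 618 without ARE-/- replicate 2. The authors' deposited table of a likelihood-ratio test lists 2015 uterus and 2954 ovary genes at an adjusted p under 0.05, and 540 of the 546 and all 1285 of the genes called here are among them. At the authors' threshold of 1e-04 the deposited tables list 514 and 719 genes, 461 and 697 of them called here, and edgeR itself called 0 and 31. Their fold changes ran opposite to ARE-/- against WT computed here, with a correlation across genes of -0.997 in the uterus and -0.9996 in the ovary, so they were not used for directions. ARE+/- and ARE-/- calls against the same WT libraries overlapped. In the uterus 241 genes were higher in both and 9 lower in both, against 8.84 and 0.0509 for independent lists, and in the ovary 330 and 76, against 20.8 and 3.61. No gene was called in opposite directions. In 20 simulations with no effect and shared WT libraries the overlap reached at most 0 genes in the uterus and 2 in the ovary. Without an effect few genes are called in either comparison, so this overlap is near 0 whatever is shared and gives no baseline. The log2 fold changes of the 2 comparisons had a covariance of 0.758 in the uterus and 0.485 in the ovary. The simulations gave 0.169 and 0.104, which is 0.589 and 0.381 less. Correlations of these fold changes were 0.764 and 0.791, beside simulated ones of 0.498 and 0.499. The simulations drew genes independently, from means common to all genotypes. Shared WT libraries may therefore add more in the real data, above all for genes near 0 counts in WT. The 3 WT libraries are too few to divide between the comparisons, so part of the excess over independent lists may come from sharing them.

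The last question was whether the tissues responded alike. Among 22575 genes tested in both, 452 rose in both ARE-/- tissues and 7 fell in both, against 54.3 and 4.09 for independent lists, and 4 went opposite ways. The correlation of fold changes across genes, which are not independent replicates, was 0.419. Of the 452, 56 were on the interferon gamma, MHC or type I interferon lists. The difference between the tissues was tested by an interaction over all 18 libraries, which called 45 of 26682 genes, 16 with the higher effect in the ovary and 29 with the higher effect in the uterus. All libraries were treated as independent here. With the replicate number as a block fewer genes were called, as given with the other alternatives below. In simulations the interaction test recovered 44% of genes changed 4-fold and 0% of genes changed 2-fold, so differences of that size could be missed. Ccr3, Ripor2 and Kcng1 had the largest differences towards the ovary (5.33, 3.21 and 2.79 on the log2 scale). Ces1f, a carboxylesterase, Mrap, a partner of the melanocortin receptor in adrenal and fat cells, and Nr1h4, the bile acid receptor, had the largest towards the uterus (-6.40, -6.21 and -5.66). The calls of Ccr3, Ripor2 and Kcng1 were lost in 18, 18 and 6 of 28 alternatives, and those of Ces1f, Mrap and Nr1h4 in 19, 16 and 9. For the interferon gamma response list no difference between tissues was called (0 of 35 genes, median difference -0.04, camera adjusted p = 0.9). Natural killer genes lay higher in the ovary effect (median 1.74, 0 of 10 called, 8 adjusted over the list alone), a camera call lost with an estimated correlation (adjusted p = 0.2). The effect on Ifng was 4.92 in the uterus and 4.03 in the ovary, a difference that was not called (edgeR adjusted p = 0.79). The count of 45 was 19, 377 and 7 without uterus WT replicates 1, 2 and 3, 25 without uterus ARE+/- replicate 2, 236 and 369 without uterus ARE-/- replicates 1 and 2. It was 3, 8 and 25 without ovary WT replicates 1, 2 and 3, 17 and 24 without ovary ARE+/- replicates 1 and 2, and 3, 18 and 17 without ovary ARE-/- replicates 2, 3 and 6.

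**Figure D3:**
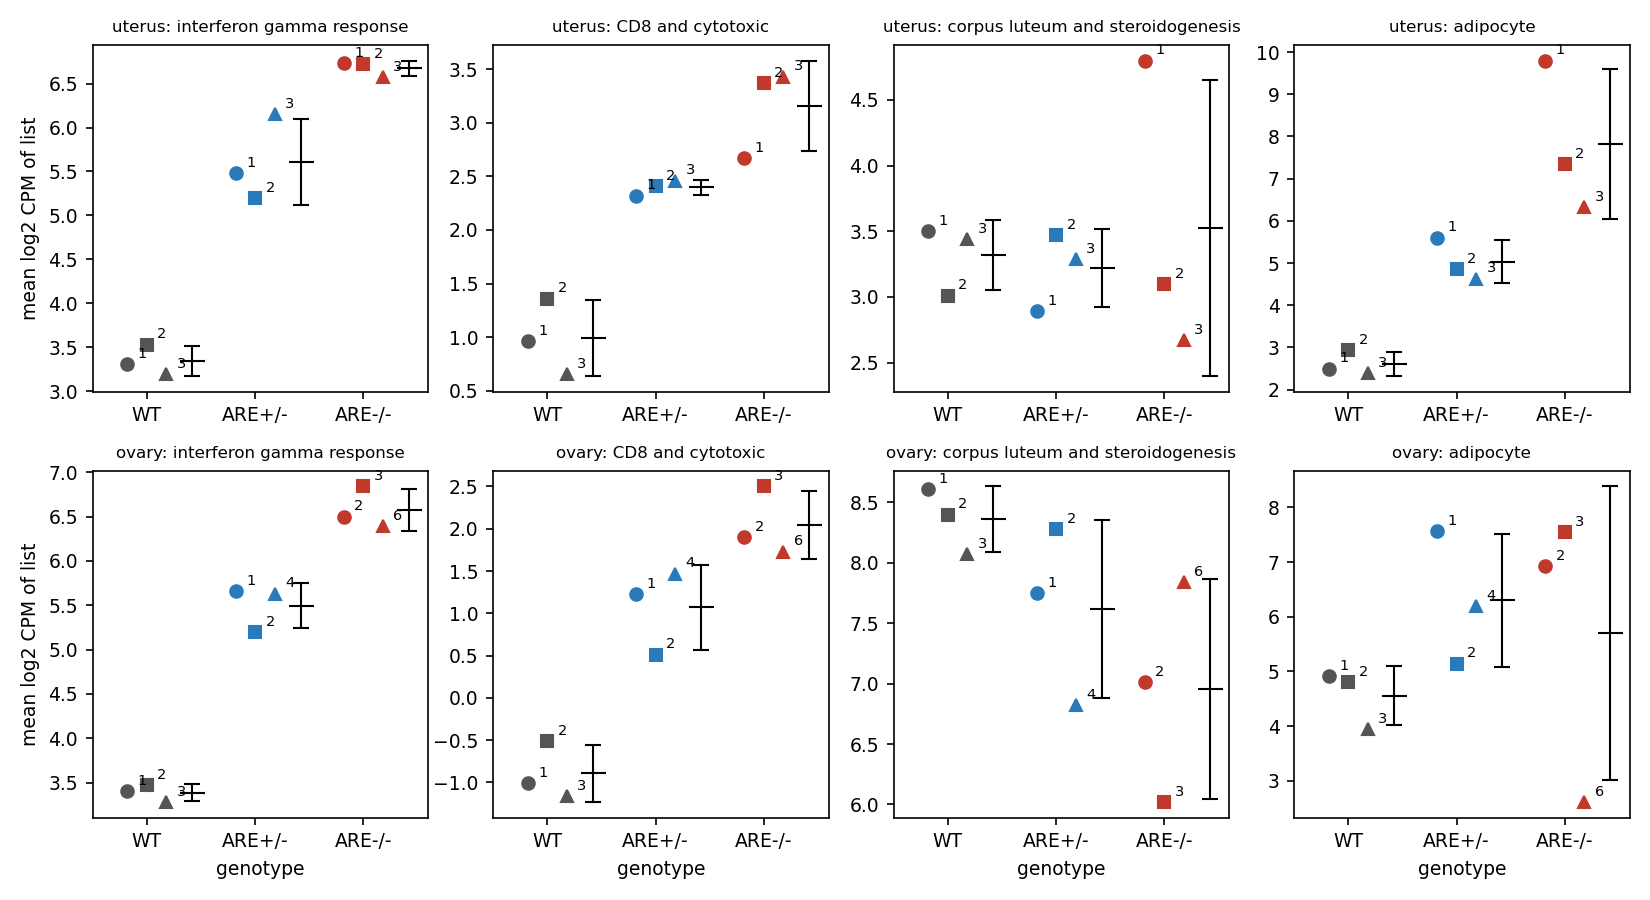
Mean log2 CPM of 4 gene lists (vertical axis, scale differs between panels) by genotype (horizontal axis) in uterus (top) and ovary (bottom); points are single libraries with their replicate numbers and black bars the mean ± SD of 3. Interferon gamma response and CD8 lists lie higher in every ARE-/- library than in any WT library, every ARE-/- ovary lies below every WT ovary on the luteal list, ARE-/- ovary 3 lowest, and adipocyte genes are highest in ARE-/- uterus 1.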

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

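The tests of whether 1 library holds the fat cell rise, of ovarian tissue in uterus ARE-/- replicate 1, and both tests on luteal genes were chosen after the result was seen; the tests of other splits of the samples and of other fat cell genes were set before theirs were. The single genes given as examples of fat and ovarian transcripts were chosen after their values were seen.

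The effect of the ARE-/- genotype differed between ovary and uterus by an interaction test for 45 genes, led by Ccr3, Ripor2 and Kcng1 (5.33, 3.21 and 2.79 on the log2 scale, ovary minus uterus) and by Ces1f, Mrap and Nr1h4 (-6.40, -6.21 and -5.66). Of 100 drawn splits of the libraries, 7, the real one included, gave as many genes, and the highest of the others gave 1174. The split with 1174 keeps the 3 ARE-/- uteri together and mixes ovary genotypes, so it carries the genotype effect of 1 tissue and is not a case without change. By the rule set for this test beforehand, 7 of 100 splits fits chance as a source of the 45 genes. The split with 1174 makes that share an uncertain guide, and the make-up of the other splits is not described here. Chance is therefore not argued against for these 45 genes, and this stays open. In the fit with the real labels Ces1f, Mrap and Nr1h4 were higher in ARE-/- uterus by 7.93, 5.79 and 4.16, the tissue with the fat and ovarian transcripts described next.

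Fat cell transcripts were higher in ARE-/- uterus. The mean log2 CPM of the adipocyte list was 2.50, 2.93 and 2.39 in WT replicates 1 to 3, 5.60, 4.86 and 4.63 in ARE+/- and 9.80, 7.35 and 6.33 in ARE-/- replicates. A rise held by ARE-/- replicate 1 alone is argued against, since 8 of the 10 adipocyte genes measured without it were called. Fat cells in the libraries would bring their other transcripts, and 19 further genes abundant in fat, listed before their values were seen, had a median log2 fold change of 3.61, with 15 called and 18 higher in all 3 ARE-/- libraries than in all WT (chance gives 1 in 20); Lpl rose by 4.51 and Adig by 6.77. Fat cells are therefore a candidate source, while whether more fat was dissected with the ARE-/- uterus or the tissue itself changed stays open.

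Uterus ARE-/- replicate 1 carried ovarian transcripts. Of 44 genes abundant in ovary and near absent from the other 8 uteri, 42 were above the highest of those, at a median of 6.26% of the ovary level (quartiles 2.48% and 9.86%), including Amh at 39.6 CPM (23.2%), Hsd3b1 at 120 CPM (4.58%) and Zp3 at 4.14 CPM (18.0%). For each of the other 8 libraries the same rule left 6 genes, with at most 2 above the rest. ARE-/- replicate 1 was then among the libraries compared. Its own ovarian transcripts removed genes and raised the level to exceed, so this is not an equal control. The luteal transcripts Cyp11a1 and Star were lower, at 1.22% and 1.96%, the latter below the highest other uterus. Hsd3b1, of the same luteal list, lay between the quartiles at 4.58%. A piece of ovary in that library is a candidate explanation, and no biological explanation was tested. Removal of that library left 1103 called genes for ARE-/- against WT, 749 of them shared with the 911.

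The luteal list lay below all 3 WT ovaries (8.07 to 8.61) in every ARE-/- ovary, by most in replicates 2 and 3 (7.01 and 6.02) and by least in replicate 6 (7.84), and it was also low in ARE+/- replicate 4 (6.82). The adipocyte list was high in ARE-/- ovaries 2 and 3 (6.92 and 7.55) and low in replicate 6 (2.61), against 3.94 to 4.92 in WT and 7.56, 5.14 and 6.20 in ARE+/- replicates 1, 2 and 4, so differing amounts of fat or other tissue in the ovary samples stay open as well, untested. A wild-type library under the name of replicate 6 is argued against, as 34 of its 34 interferon gamma response genes were above all 3 WT. Differences between single ovaries that do not follow genotype, such as the stage of the estrous cycle, cannot be told apart from a genotype effect: 1 of 10 splits, the real one at -1.40, gave a difference as large, the highest other gave 1.25 in size, and 10 splits are too few for a share under 0.05.

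For the counts of called genes, 10 splits of 6 libraries are likewise too few for a share under 0.05. The real and the highest other counts were 911 and 18 for ARE-/- against WT and 276 and 0 for ARE+/- against WT in the uterus, and 2558 and 0, and 417 and 0, in the ovary, where 1 of 10 splits reached the real count each time. For ARE-/- against ARE+/- they were 0 and 5 in the uterus, where all 10 splits reached the real count, and 12 and 630 in the ovary, where 2 did. The split with 630 sets ovary ARE+/- replicate 4 with ARE-/- replicates 2 and 3 against the rest, which points to a structure of the samples. For any genotype difference 1 of 100 drawn splits, the real one, reached the real count in each tissue. The counts were 546 against 303 at most in the uterus and 1285 against 601 in the ovary. This share is under 0.05, so chance is argued against. It is not excluded, since the real split is always among those drawn and no smaller share was possible.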

How the results depend on the processing

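All alternatives here were planned. One limit is the number of libraries: 3 per group left counts of called genes dependent on single libraries, and in simulations edgeR recovered 5% of 2-fold changes in the uterus and 37% in the ovary for ARE-/- against WT. Directions did not turn in any alternative for the called genes that were tracked, which leave out, among others, ARE-/- against ARE+/- and most genes named for ARE+/- against WT. Under settings other than leaving a library out, most checks of named genes for ARE-/- against WT kept both the sign and the side of the threshold. These were 843 of 927 checks of 94 genes in the uterus and 940 of 1029 checks of 104 in the ovary. With a library left out, both were kept in 689 of 846 and 836 of 936 checks. The cause of the shifts below was not tested except where stated.

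DESeq2 called 2407, 1363, 186 and 2071 genes in the uterus (ARE-/- against WT, ARE+/- against WT, ARE-/- against ARE+/-, any difference), 4139, 1500, 199 and 3225 in the ovary, and 824 for the tissue difference. On simulated data 35.8% (uterus) and 24.3% (ovary) of its ARE-/- against WT calls fell on unchanged genes. These simulations used edgeR's dispersions, so the shares may favour edgeR and need not hold for the real counts. limma-voom called 592 and 155 for the uterus comparisons with WT and 353 for any difference, 148 for ARE+/- against WT and 19 for ARE-/- against ARE+/- in the ovary, and 18 for the tissue difference. Fits to the pair of genotypes alone, with fewer libraries, called 374 and 922 in the uterus and, in the ovary, 701 for ARE+/- against WT and 0 for ARE-/- against ARE+/-. The tissue difference without the 6 ARE+/- libraries called 5. Against a fold of 1.5 (glmTreat, a stricter question) the counts were 466 and 102 in the uterus, 419, 80 and 0 in the ovary, and 3 for the tissue difference. At 1e-04 the tests of any difference called 0 and 31. With no low-count filter ARE+/- against WT gave 415 and ARE-/- against ARE+/- 1 in the uterus and 38 in the ovary. That last comparison, 12 genes in edgeR as run, gave 0 with a mean CPM of at least 1, 0 without robust estimation and 6 without abundant RNAs. With an estimated correlation 7 uterus and 6 ovary lists passed in place of 23 and 26.

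Leaving out 1 library gave 192 to 1322 genes for ARE-/- against WT, 0 to 733 for ARE+/- against WT, 0 to 1 for ARE-/- against ARE+/- and 84 to 777 for any difference in the uterus. In the ovary the ranges were 785 to 3262, 75 to 727, 0 to 14 and 210 to 1806, and for the tissue difference 3 to 377. Among genes that were not called, the sign turned for Gzmb (-0.74 to 0.43), Ihh (-1.39 to 0.64), Areg (-2.25 to 2.77; 0.83 with limma-voom), Lcn2 (-0.48 to 2.57) and Foxa2 (-0.04 to 0.71) in the uterus, and for Gdf9 (-0.41 to 0.46) and Mki67 (-0.11 to 0.24) in the ovary.

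Groups share replicate numbers, but the numbers did not pair the samples by the rule that every same-numbered pair correlates over 0.1. Deviations from group means correlated at -0.026 to 0.45 in the uterus (7 of 9 pairs over 0.1, 13 of 18 best with their own number) and at -0.28 to 0.0064 in the ovary (0 of 5, and 0 of 10 best). Between tissues, same-numbered libraries of a genotype correlated at 0.034 to 0.29 (5 of 7 over 0.1), against -0.25 to 0.19 for different numbers (2 of 20 over 0.1). The labels do not say whether these share a mouse, and the test of the tissue difference treats all libraries as independent. With the number as a replicate block the counts were 765, 302, 0 and 459 in the uterus, 1544, 59, 0 and 715 in the ovary and 13 for the tissue difference, and Gdf9 in the ovary was at -0.31. Numbers 4 and 6 occur in a single ovary library each, which the block fits by itself. Ovary ARE+/- replicate 4 and ARE-/- replicate 6 therefore add nothing to the contrasts of these block fits.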

Other observations

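Of 6 eosinophil genes 1 rose in ARE-/- uterus, Prg2, a granule protein (1.95 ± 0.45, edgeR adjusted p = 0.045; not followed through the alternatives), and the list did not pass there (median -0.23, camera adjusted p = 0.7). Siglecf, a receptor of eosinophils, rose in ARE+/- uterus from 1.87 ± 0.382 to 6.97 ± 0.342 CPM (1.90 ± 0.37, edgeR adjusted p = 0.047) and was at 1.95 ± 0.925 CPM in ARE-/- uterus. The ARE+/- call ended without WT replicate 3, when 0 genes of that comparison were called. Ccr3 rose in ARE-/- ovary by 4.83 ± 0.75 and gave -0.52 ± 0.53 in ARE-/- uterus (adjusted p = 0.64). Gata2, a transcription factor of the endometrium and of blood progenitors, rose in ARE-/- ovary from 29.8 ± 3.58 to 55.4 ± 3.58 CPM (adjusted p = 0.0016) and was at 165 ± 62.2 and 95.7 ± 16.0 CPM in WT and ARE-/- uterus, where it was not called (adjusted p = 0.14). Among neutrophil markers S100a9, a calcium-binding protein of neutrophils, rose in ARE-/- uterus by 6.07 ± 1.28 (adjusted p = 0.035), and its partner S100a8 was at 1.12 ± 0.536 CPM in WT and 43.5 ± 10.3 CPM in ARE-/- uterus without a call (adjusted p = 0.053). The call of S100a9 ended without WT replicates 1, 2 or 3, ARE+/- replicates 1 or 2, or ARE-/- replicates 1 or 3, at adjusted p of up to 0.187. With the other settings counted too, it was lost in 11 of 19 alternatives. The neutrophil list gave 2 rises of 9 in ARE-/- uterus (adjusted p = 0.16 with an estimated correlation).

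Checkpoint and lymphoid signals were also measured. Ctla4, an inhibitory receptor of T cells, rose in ARE-/- uterus from 0.0460 ± 0.0477 to 1.15 ± 0.338 CPM (adjusted p = 0.02), a call that ended without WT replicate 1, WT replicate 3 or ARE-/- replicate 3 (adjusted p of up to 0.0650), and 3 of 12 genes of that list rose (7 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation). Tnfsf13b, the B cell survival factor BAFF, rose in ARE-/- ovary from 2.20 ± 0.203 to 12.7 ± 2.90 CPM (adjusted p = 0.00035), and Ccl19, a chemokine of lymphoid tissue, rose there by 3.37 ± 0.56 (adjusted p = 0.0066); 4 of 8 lymphoid chemokine and venule genes rose (adjusted p = 0.18 with an estimated correlation). Mup14 in the ovary, like Gata2 in the ovary, was chosen after its values were seen. With 0 counts in WT ovary, it was at least 74.8-fold higher in ARE-/- ovary and at least 71.1-fold higher in ARE+/- ovary, but was called in neither (edgeR adjusted p = 0.14 and 0.25).

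In the authors' deposited tables, clusters 1, 2, 3 and 4 of the uterus hold 463, 11, 38 and 2 genes, with median ARE-/- against WT log2 fold changes computed here of 2.77, 4.02, -2.39 and -0.12. Clusters 1, 2 and 4 of the ovary hold 569, 147 and 2 genes, with medians of 1.98, -0.69 and 0.65.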
